A study of Mus musculus with 168 samples.

How the data were processed

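The series follows peripheral blood mononuclear cells of healthy BALB/c mice, sampled repeatedly over 3 weeks, by bulk RNA-seq of polyadenylated RNA. The 4 arms are the IL12ns vector at doses labelled 10 mg and 0.1 mg, daily IL-12 at 10000 ng/kg/day as the positive control, and control. Each arm has 42 libraries, 21 from females and 21 from males, spread over 7 times coded t1 to t7. Groups hold 6 libraries, except control at t1 with 5 (2 female) and control at t2 with 7 (4 female). Whether 1 female control library of t1 carries a label of t2 cannot be told from the files, which would affect all contrasts at these times. The sources used here give neither the day of each code nor whether t1 comes before the first dose, and they name no animals. No paired analysis was possible because no label names the animal of a library. In parts the library numbers run through the times in cycles within an arm and sex, which may follow animals. The order is broken elsewhere and its meaning is not stated, so it was not used to link libraries. Libraries of different times may share an animal, and all tests treat them as independent, including the F tests and comparisons of 2 times. The p values of contrasts averaged over times may therefore be too small. A dose of 0.001 mg is named in the design text and has no libraries here.

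The submitters' processing notes name featureCounts of Subread for counting reads per gene on mm10. The aligner, the annotation release and all versions are not given in the sources used here. The deposited values are log2(RPKM + 1) with 0.0001 added, for 21073 genes, and 34.0% of them equal the added constant. The design, written before the data were examined, had assumed log2(RPKM + 1) if the file held RPKM and a test on counts if it held counts. The values fit the first, so the added constant was taken off and no further scaling was applied. RPKM is scaled by library size, so all comparisons are of relative levels. Whole read numbers could be recovered from the values for 15738 of 15740 genes found in at least 20 libraries (99.99%, within 0.05 reads of a whole number). Reads summed over the listed genes had a median of 69.2 M (11.4 to 321.6 M). The medians were 63.2 M in the daily IL-12 arm, 73.2 M at 10 mg, 58.5 M at 0.1 mg and 72.6 M in control.

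Library numbers fall in 2 runs, of 82 and 86 libraries, with median depths of 44.5 M and 91.6 M reads. The runs are uneven over the times: the 10 mg libraries of t1, t2 and t5 all come from the second run and those of t4, t6 and t7 from the first. A term for the run was therefore part of each model, and values within a run are given beside the pooled ones. The permutation tests of scores hold no such term, although arm and control of a time often come from different runs. At t4, for example, the first run holds 6 libraries of 0.1 mg and 2 of control. Whether the runs match the 5 sequencing kits is not stated.

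Genes with an RPKM of at least 1 in at least 5 libraries were tested (11734 genes). The main test was limma with an intensity trend and robust variances on log2(RPKM + 1), in 1 fit of all libraries with the 28 groups, sex and run. Contrasts were the mean over the 7 times, each time, 10 mg against 0.1 mg, and daily IL-12 against 10 mg, followed by F tests for effects that differ between times, sex differences of each effect, and change over time within control. Adjusted p values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Fold changes are log2 on the log2(RPKM + 1) scale with the standard error, so they understate changes of genes with low levels.

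Fixed lists, part of the same design, cover 11 programmes: IFN-gamma-induced genes, MHC class I processing, MHC class II presentation, type I interferon-induced genes, the IL-12 receptor, STAT4 and Th1 programme, cytotoxic effector genes, checkpoint receptors, proliferation, inflammatory cytokines and NF-kB feedback, immediate early and heat shock genes, and naive lymphocyte genes. A further 13 lists are markers of NK cells, T cells, B cells, plasma cells, classical and non-classical monocytes, neutrophils, conventional and plasmacytoid dendritic cells, basophils, eosinophils, erythroid cells and platelets. Each list was tested with camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with adjustment over the lists of a contrast. Scores per library are means of log2(RPKM + 1) over a list, compared by exact two-sided permutation tests and adjusted over the 21 comparisons of a list. The IFN-gamma score was planned, and the neutrophil and B cell scores were added after the results were seen. The Th1 and inflammatory lists share 1 gene, Tnf.

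Genes are named by a rule of that design. Each arm against control, as the mean over times, gives its 10 largest increases and 8 largest decreases with an adjusted p under 0.05 and a mean RPKM of at least 1. Each arm at its time with most calls gives 5 increases and 3 decreases, the 2 direct contrasts 5 and 5, and each F test or sex difference the 3 smallest p values. Predicted genes, ribosomal and mitochondrial genes and receptor segments are left out. Always named are Ifng, Il12a, Il12b, Il12rb2, Cxcl9, Cxcl10, Gbp2, Gzmb, Prf1, Il10, Cd274, Socs1, Xist and Ddx3y, and 2 to 4 members stand for a list. Xist is not in the file, and Il12b stayed below the filter (highest RPKM 0.945, above 0 in 30 libraries). The names of 20857 genes were matched by Entrez number to RefSeq on GRCm38.p6.

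A self-test drew simulated libraries with the mean and spread of each real gene, then moved 200 genes in the daily IL-12 arm. As the mean over times it called 54 of 58 genes moved 1.5-fold, 73 of 73 moved 2-fold and 69 of 69 moved 4-fold; at t3 alone it called 14, 60 and 69. False calls were 9 and 13 of 11534 genes. The moved list was called by 3 list tests: camera with the preset correlation, camera with an estimated one, and fry. Camera with the preset correlation called 0 of 20 unmoved lists. The results of fry on the real lists are not given here. All simulated values were independent draws, without correlation between genes and without effects of sex, run or animal. These rates are therefore not the error rates of the real data, whose lists hold correlated genes.

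Ddx3y reached at most 0.27 in the 84 libraries labelled female (mean 0.01) and at least 2.17 in the 84 labelled male (mean 3.33), so all labels of sex match. No 2 libraries were identical (highest correlation 0.988). The median correlation of a library with its own group was 0.972 in the middle of all libraries and 0.881 at the lowest. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. After the data were seen, 3 alternatives were added: median-ratio scaling, limma-voom on the recovered reads, and leaving out the 5 libraries with a median correlation under 0.92 to their group.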

Results

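Blood mononuclear cells of mice given daily IL-12 or the IL12ns vector were compared with control at 7 times, with 42 libraries in each arm and 5 to 7 in each group. Fold changes below are log2 with the standard error from limma, and adjusted p values are Benjamini-Hochberg values over 11734 tested genes unless a list is named. The median shift of all genes was 0.12 for daily IL-12, −0.11 for 10 mg and 0.13 for 0.1 mg against control, and close to 0 after quantile normalization. Small fold changes and the balance of higher and lower calls should be read relative to these shifts.

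Daily IL-12 raised genes that IFN-gamma switches on. Among the 10 largest increases, as the mean over the 7 times, were 4 guanylate-binding proteins and immunity-related GTPases, which attack vacuoles that shelter microbes inside cells. These are Gbp2b (3.46 ± 0.11, adjusted p = 3.19e-64), Gbp2 (3.23 ± 0.10), Iigp1 (2.97 ± 0.09) and Gbp5 (2.81). Ly6a, a surface marker that interferon induces on lymphocytes, rose by 3.23 ± 0.11, and Serpina3g, a protease inhibitor of activated T cells, by 2.94 ± 0.11. Oasl2 (3.20 ± 0.09), Zbp1 (2.72) and Ifit3b (2.53), which act in the sensing and restriction of viral nucleic acid, rose with them, as did the monocyte marker Ly6c2 (2.45 ± 0.12). Of the fixed list of IFN-gamma-induced genes 30 of 31 rose (30 adjusted over the list alone). Their median was 1.88 (camera adjusted p = 1.86e-122, and adjusted p = 7.65e-10 with an estimated correlation). Type I interferon-induced genes rose in 23 of 24 cases (median 1.42, camera adjusted p = 5.22e-62, and adjusted p = 4.00e-08 with an estimated correlation). Ifit3 (2.12) and Rtp4 (2.10) were among them. All 14 genes of MHC class I processing, which cut and load the peptides shown to CD8 T cells, rose (median 1.18, camera adjusted p = 6.02e-36, and adjusted p = 5.25e-04 with an estimated correlation). Examples are B2m (1.85), Nlrc5 (1.85), Psmb9 (1.79) and Tap1 (1.70). Of 12 genes of MHC class II presentation only 2 rose (median 0.14, camera adjusted p = 0.94).

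Single mediators of the IL-12 and IFN-gamma axis also rose with daily IL-12. Socs1, a feedback inhibitor of cytokine signals, rose by 1.88 ± 0.10. Cxcl10 (2.18 ± 0.09) and Cxcl9 (1.14 ± 0.04) encode chemokines that draw activated T cells, Cd274 (1.82 ± 0.09) the checkpoint ligand PD-L1, and Il10 (0.64 ± 0.04) a cytokine that limits inflammation. Ifng itself rose by only 0.24 ± 0.08 (adjusted p = 0.0146), the receptor gene Il12rb2 by 0.25 ± 0.08 (adjusted p = 0.014) and the pore-forming gene Prf1 by 0.56 ± 0.10. Gzmb (0.19, adjusted p = 0.168) and Il12a (0.16, adjusted p = 0.328) did not pass. The IL-12 receptor, STAT4 and Th1 programme split into 10 higher and 3 lower of 20 (12 and 3 adjusted over the list alone; median 0.24, camera adjusted p = 0.025, adjusted p = 0.666 with an estimated correlation). Il18bp (1.85), an inhibitor of IL-18, was among the higher genes. Cytotoxic effector genes had 6 of 11 higher (median 0.28, camera adjusted p = 0.146), checkpoint receptors 5 of 9 (0.20, camera adjusted p = 0.287) and inflammatory cytokines and NF-kB feedback 8 of 12 (0.37, camera adjusted p = 0.0561). Proliferation had 4 higher and 2 lower of 16 (median 0.12, camera adjusted p = 0.353), immediate early and heat shock genes 2 and 1 of 12 (0.03, camera adjusted p = 0.344), and naive lymphocyte genes 1 and 1 of 9 (−0.20, camera adjusted p = 0.053).

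Markers of myeloid cells rose with daily IL-12 and markers of red cells fell. Classical monocyte markers rose in 9 of 10 cases (median 0.80, camera adjusted p = 4.69e-08, adjusted p = 0.0866 with an estimated correlation). Chil3 (1.59), Ms4a6c (1.15) and Ccr2 (1.05), the receptor that lets monocytes leave the marrow, stand for them. Neutrophil markers rose in 10 of 13 cases (median 0.88, camera adjusted p = 9.44e-04, adjusted p = 0.603 with an estimated correlation). Ly6g rose by 1.54 and the granule genes Ngp and Ltf by 1.11 and 1.03. The list lay as high at t1 (median 0.96, 0 of 13 past the threshold) as at t6 (1.01), and the neutrophil score was 1.08 above control at both (exact p = 0.0563 and 0.00216). Erythroid markers fell in 7 of 10 cases (9 adjusted over the list alone; median −0.45, camera adjusted p = 1.70e-07, adjusted p = 0.0943 with an estimated correlation). The anion exchanger Slc4a1 (−0.71) and the globin gene Hbb-bs (−0.50) were among them. The largest single decreases were Hsd3b6 (−0.86 ± 0.10) of steroid synthesis, Pcx (−0.86 ± 0.15), the pyruvate carboxylase gene, and Sptb (−0.84 ± 0.13) of the red cell skeleton. Next came Acmsd (−0.77), Urod (−0.75) of haem synthesis, Prdx2 (−0.74), Cd59a (−0.72) and Apoe (−0.71). T cell markers passed in 0 of 14 cases (median −0.13, camera adjusted p = 0.00347, adjusted p = 0.666 with an estimated correlation). B cell markers were lower in 2 of 14 (0 adjusted over the list alone; −0.10, camera adjusted p = 0.00547, adjusted p = 0.666 with an estimated correlation). Plasmacytoid dendritic cell markers were lower in 1 of 6 cases (median −0.16, camera adjusted p = 0.021, adjusted p = 0.547 with an estimated correlation). NK cell markers were higher in 5 and lower in 1 of 15 (0.02, camera adjusted p = 0.527), and non-classical monocytes higher in 3 of 9 (0.01, camera adjusted p = 0.527). Conventional dendritic cells had 4 higher and 2 lower of 6 (0.24, camera adjusted p = 0.344), and plasma cells 2 and 1 of 6 (−0.05, camera adjusted p = 0.527). Basophil markers were higher in 4 of 7 (6 adjusted over the list alone; 0.31, camera adjusted p = 0.258), platelets in 3 of 11 (7 adjusted over the list alone; 0.38, camera adjusted p = 0.363) and eosinophils in 0 of 5 (−0.13, camera adjusted p = 0.0561).

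Over all genes 4217 passed for daily IL-12 as the mean over times, 3711 higher and 506 lower, and 171 of them changed at least 2-fold. The share of higher calls was 88.0% as deposited, 40.7% after quantile normalization, 41.7% with median-ratio scaling and 48.1% with limma-voom (4196 genes). The medians of the MHC class II, proliferation, immediate early, NK cell and non-classical monocyte lists turn negative under these scalings. Within the first run of library numbers (t3, t5 and t6) 2333 genes passed and the IFN-gamma list had a median of 2.46. Within the second (t1, t2 and t4) these were 1003 and 1.38.

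Interferon-induced genes passed for daily IL-12 at each time from t2 on and not at t1. At t1 limma called 0 genes (680 with an unadjusted p under 0.05, 0 by limma-voom), and the IFN-gamma list had a median of 0.07. From t2 to t7 that median was 1.94, 2.68, 2.20, 2.31, 2.33 and 1.29, with 30, 30, 29, 30, 30 and 27 of 31 genes higher. The IFN-gamma score per library was 2.52 ± 0.14 (mean ± SD) at t1 against 2.4 ± 0.14 in control (exact p = 0.206). It was 4.21 ± 0.20 against 2.19 ± 0.40 at t2 (exact p = 5.83e-04), 4.78 ± 0.24 against 2.23 ± 0.38 at t3 (exact p = 0.00216) and 3.41 ± 0.39 against 2.17 ± 0.38 at t7 (exact p = 0.00433; adjusted p = 0.0114). At t3 the largest changes were Gbp2b (4.64 ± 0.29), Iigp1 (4.47), Oasl2 (4.42), Gbp2 (4.21) and Ly6a (4.21) upward. Pcx (−1.54), Hsd3b6 (−1.38) and the antioxidant gene Prxl2a (−1.31) fell most. Killing genes rose at t3 as well. Cytotoxic effector genes rose in 10 of 11 cases (median 1.51, camera adjusted p = 1.70e-10, and adjusted p = 0.0224 with an estimated correlation). NK cell markers rose in 12 of 15 (1.01, camera adjusted p = 4.27e-10, adjusted p = 0.0546 with an estimated correlation). Prf1 rose there by 2.43 ± 0.28, the NK and T cell receptor gene Klrg1 by 2.47 ± 0.29, Gzmb by 1.56 ± 0.28 and Ifng by 1.26 ± 0.21. At t6 instead 5 NK cell markers were lower (median −0.61, camera adjusted p = 2.83e-08, adjusted p = 0.12 with an estimated correlation).

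Called genes for daily IL-12 from t2 to t7 numbered 766, 1687, 331, 516, 486 and 124, and the effect of 344 genes differed between times. Without the 5 libraries least like their group the count was lower at t2 and higher at t4 and t6. The smallest p values of that F test were those of Il10, Iigp1 and Cxcl9 (adjusted p = 2.30e-28, 6.56e-26 and 5.63e-20). Il10 rose by 2.06 ± 0.10 at t3 and by 0.58, 0.66, 0.70 and 0.44 at the 4 later times. Iigp1 rose by 1.94, 4.47, 3.75, 4.18, 4.13 and 2.39 from t2 to t7, and Cxcl9 by 1.29, 1.88, 1.19, 1.51, 1.37 and 0.82. At t3 the calls were 1522 higher and 165 lower, and the share of higher calls was 56.6% after quantile normalization, 63.3% with median-ratio scaling and 66.5% with limma-voom. At t4 limma-voom called 1546 genes instead of 331. After quantile normalization the share of higher calls went from 99% to 81.3% at t2, from 64.7% to 45.3% at t4, from 95.7% to 79.6% at t5, from 94.0% to 75.8% at t6 and from 91.9% to 81.2% at t7.

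**Figure D1:**
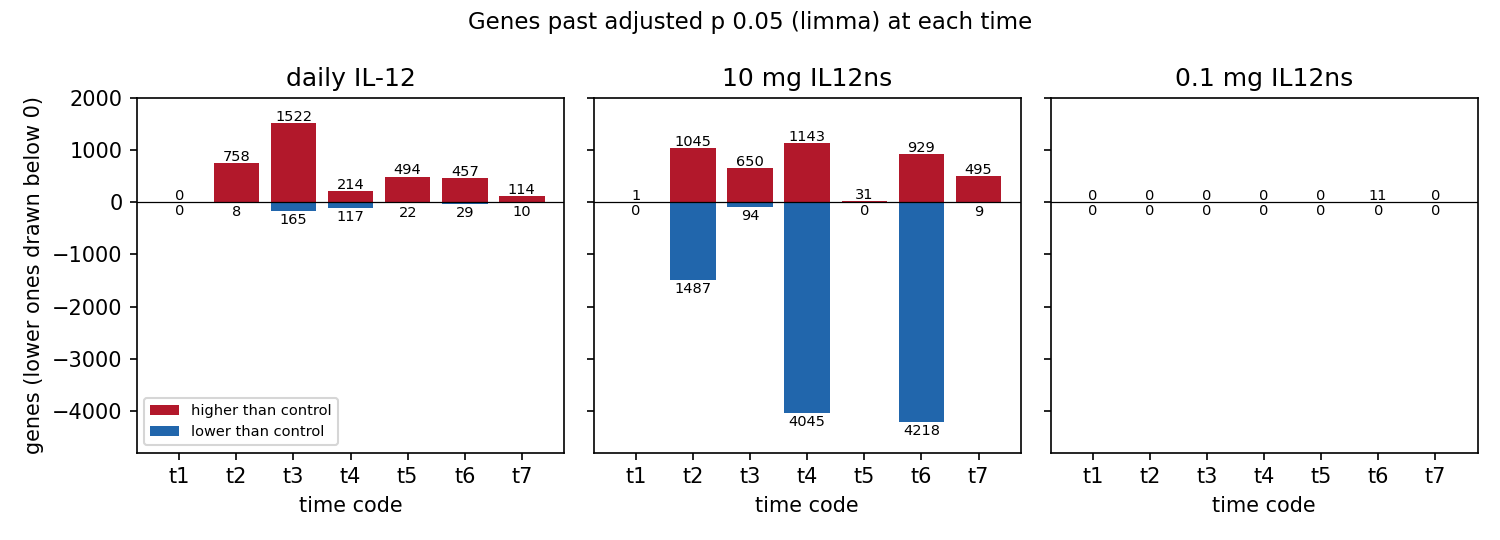
Genes past an adjusted p of 0.05 at each time, higher and lower, for each arm against control; at t6 the 10 mg arm had 929 higher and 4218 lower genes and the daily IL-12 arm 457 and 29.

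The 10 mg dose of IL12ns raised genes of neutrophils, cells that a preparation of mononuclear cells normally removes for the most part. The largest increase, as the mean over times, was that of Stfa2 (4.08 ± 0.20, adjusted p = 4.00e-40), a stefin that blocks cathepsins in neutrophils. Next were the granule gene Ngp (3.78 ± 0.21), Ly6g (3.77 ± 0.18), the surface marker of mouse neutrophils, Wfdc17 (3.76) and Prok2 (3.65 ± 0.18), a chemokine-like peptide made by neutrophils in response to G-CSF. The stefin gene Stfa3 (3.62), the granule gene Lcn2 (3.56 ± 0.20), whose product withholds iron from bacteria, the stefin gene Cstdc5 (3.53), Wfdc21 (3.49) and the uridine phosphorylase gene Upp1 (3.39) complete the 10 largest. All 13 neutrophil markers rose (13 adjusted over the list alone). Their median was 2.58 (2.48 after quantile normalization, 2.99 with limma-voom; camera adjusted p = 4.48e-29, and adjusted p = 0.0023 with an estimated correlation). Classical monocyte markers rose in 9 of 10 cases (median 0.51, camera adjusted p = 3.62e-06, adjusted p = 0.396 with an estimated correlation). Chil3 (1.65), the endotoxin co-receptor Cd14 (1.63) and Vcan (1.38) stand for them. IFN-gamma-induced genes rose in 17 and fell in 3 of 31 (median 0.28, camera adjusted p = 5.35e-08, adjusted p = 0.396 with an estimated correlation). Among the higher ones were Gbp2b (1.77 ± 0.11), Gbp2 (1.60 ± 0.10), the nitric oxide synthase gene Nos2 (1.27 ± 0.07) and Fcgr4 (1.17). Type I interferon-induced genes had 15 higher and 1 lower of 24 (median 0.25, camera adjusted p = 9.80e-07, adjusted p = 0.396 with an estimated correlation), with Oas2 at 1.41. MHC class I processing had 6 higher and 1 lower of 14 (0.14, camera adjusted p = 0.0454, adjusted p = 0.742 with an estimated correlation).

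Genes of B cells and of MHC class II presentation fell at 10 mg. All 14 B cell markers fell (14 adjusted over the list alone). Their median was −1.07 (−1.16 after quantile normalization, −0.99 with limma-voom; camera adjusted p = 1.81e-08, adjusted p = 0.396 with an estimated correlation). Fcer2a, the low-affinity IgE receptor (−1.30 ± 0.16), Fcrla (−1.19 ± 0.14) and Cd79b of the antigen receptor (−1.15 ± 0.14) were among the largest decreases, with the IgM receptor gene Fcmr (−1.17) beside them. MHC class II presentation fell in 11 of 12 cases (median −0.87, camera adjusted p = 7.25e-05, adjusted p = 0.511 with an estimated correlation). The invariant chain Cd74 (−0.97), H2-Aa (−0.97) and H2-Ob (−1.02) are examples. The other largest decreases were Egr1 (−1.51 ± 0.29) and Nr4a1 (−1.40 ± 0.13), transcription factors that rise within minutes of stimulation. Ptgs2 (−1.46 ± 0.19), the inducible cyclooxygenase gene, and Chst3 (−1.19) complete the 8 largest. T cell markers fell in 12 of 14 cases (median −0.61, camera adjusted p = 0.0455, adjusted p = 0.764 with an estimated correlation; Cd8a −0.70). NK cell markers fell in 11 of 15 with 1 higher (−0.50, camera adjusted p = 0.0269, adjusted p = 0.667 with an estimated correlation; Klrd1 −0.94), and cytotoxic effector genes fell in 8 of 11 with 1 higher (−0.40, camera adjusted p = 0.0968; Gzma −0.62). Non-classical monocyte markers had 7 lower and 1 higher of 9 (−0.64, camera adjusted p = 0.0485, adjusted p = 0.617 with an estimated correlation). Cx3cr1 fell by 0.83, and Pglyrp1, also a neutrophil granule gene, rose by 1.73.

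Of the single genes of the IL-12 axis, the feedback inhibitor Socs1 rose at 10 mg (0.54 ± 0.10). Ifng (−0.21 ± 0.08, adjusted p = 0.0212), Il12a (−0.60 ± 0.12, adjusted p = 1.37e-05), Il12rb2 (−0.46 ± 0.08), Gzmb (−0.40 ± 0.11) and Prf1 (−0.57 ± 0.10) fell, and the T cell and NK cell markers had medians of −0.61 and −0.50. Cxcl9 (0.03, adjusted p = 0.554), Cxcl10 (0.18, adjusted p = 0.0668), Cd274 (0.03, adjusted p = 0.783) and Il10 (0.08, adjusted p = 0.061) did not pass. The Th1 programme had 6 higher, such as the IL-18 receptor chain Il18rap (1.11), and 10 lower, such as the chemokine gene Ccl5 (−1.03), of 20 (7 and 11 adjusted over the list alone; median −0.22, camera adjusted p = 0.927). Proliferation fell in 9 of 16 (−0.26, camera adjusted p = 0.0455, adjusted p = 0.511 with an estimated correlation). Naive lymphocyte genes fell in 7 of 9 with 1 higher (−0.39, camera adjusted p = 0.275) and immediate early and heat shock genes in 5 of 12 (−0.03, camera adjusted p = 0.7). Inflammatory cytokines and NF-kB feedback had 6 higher and 4 lower of 12 (0.16, camera adjusted p = 0.369) and checkpoint receptors 1 and 2 of 9 (−0.06, camera adjusted p = 0.903). Plasma cell markers had 1 higher and 5 lower of 6 (−0.62, camera adjusted p = 0.0838), and conventional dendritic cells 4 lower of 6 (−0.48, camera adjusted p = 0.0485, adjusted p = 0.511 with an estimated correlation). Plasmacytoid dendritic cells had 4 lower of 6 (−0.38, camera adjusted p = 0.139) and erythroid cells 7 lower of 10 (−0.30, camera adjusted p = 0.275). Basophils (0 of 7, −0.10, camera adjusted p = 0.808), platelets (0 of 11, 0.26, camera adjusted p = 0.11) and eosinophils (2 higher and 2 lower of 5, 0.05, camera adjusted p = 0.839) had no shared direction.

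Over all genes 6789 passed at 10 mg, 2066 higher and 4723 lower, and 371 of them changed at least 2-fold. The share of higher calls was 30.4% as deposited, 31.3% with median-ratio scaling, 41.2% after quantile normalization and 43.6% with limma-voom (7527 genes). The medians of checkpoint receptors and basophils change sign with quantile normalization and that of immediate early genes with limma-voom. Within the first run of library numbers (t3, t4 and t6) 5419 genes passed (960 higher, 4459 lower), with medians of 3.08 for neutrophils and −1.59 for B cells. Within the second (t1 and t2) these were 2260 (1067 of them higher), 2.58 and −0.85.

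The response to 10 mg went up and down over the times. Lipg, an endothelial lipase gene, rose by 5.13, 5.93 and 5.84 at t2, t4 and t6 and lay at 0.33, 0.09 and 0.12 at t3, t5 and t7. Nos2 followed with 2.59, 2.70 and 2.67 against 0.40, 0.07 and 0.13, and the lipase gene Pnpla1 with 1.28, 1.46 and 1.29 against 0.23, 0.05 and 0.14. These had the smallest p values among 2088 genes whose effect differed between times (adjusted p = 3.95e-38, 2.12e-28 and 8.28e-29). Neutrophil markers had medians of 1.17, 3.46, 1.89, 3.77, 1.70, 4.26 and 2.32 from t1 to t7, with 0, 12, 13, 12, 4, 13 and 12 of 13 higher. Their score per library was 8.55 ± 1.65 against 5.34 ± 0.63 in control at t2 (exact p = 0.00291). It was 9.27 ± 0.67 against 5.58 ± 0.43 at t4 and 8.96 ± 0.48 against 4.78 ± 0.29 at t6 (exact p = 0.00216 each), and 7.33 ± 0.30 against 5.18 ± 0.58 at t7 (exact p = 0.00216). B cell markers moved in the opposite direction, with medians of −0.57, −1.07, −0.05, −2.34, −0.55, −2.30 and −0.71 and 0, 12, 0, 14, 0, 14 and 0 of 14 lower. Their score per library passed only at t4 (3.84 against 6.35 in control) and t6 (3.36 against 5.63; exact p = 0.00216 and adjusted p = 0.0227 each), and not at t2 (4.60 against 5.71, exact p = 0.101; adjusted p = 0.355). MHC class II presentation reached −2.14 at t4 (12 of 12 lower) and −1.97 at t6. At t4 the largest changes were Prok2 (7.07 ± 0.52), Lipg (5.93 ± 0.34), Ngp (5.81), Ifitm6 (5.65) and Lcn2 (5.55) upward. Fcer2a (−2.84), Nr4a1 (−2.53) and the B cell regulator Pax5 (−2.49) fell most.

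**Figure D2:**
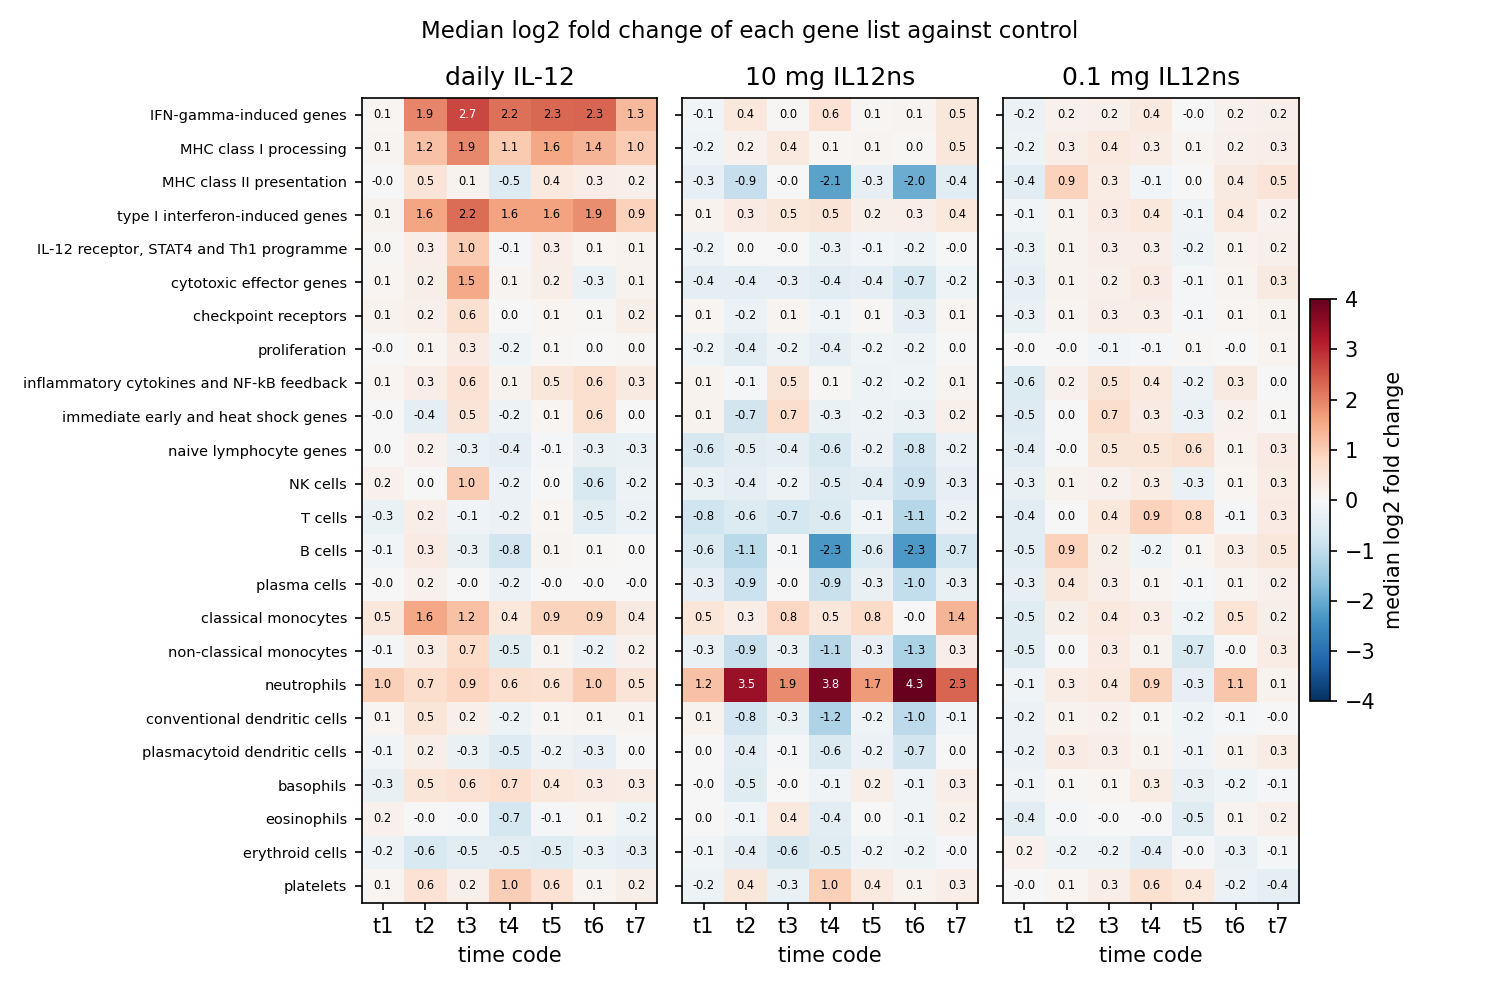
Median log2 fold change of each fixed list against control at t1 to t7 in each arm; neutrophil markers at 10 mg reach 3.46, 3.77 and 4.26 at t2, t4 and t6.

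Called genes at 10 mg numbered 1 at t1, 2532 at t2, 744 at t3, 5188 at t4, 31 at t5, 5147 at t6 and 504 at t7. The gene at t1 was Best1, named here after the result was seen, and limma-voom called 628 genes there. Limma-voom also gave larger counts at t2 (5036), t3 (1421) and t7 (1.1e+03). The count at t3 depends on the fit: it was 35 in a fit of the compared arms only, 2838 without the 5 libraries least like their group, 2214 with no term for the run and 3 within the first run, which holds 2 of the 10 mg libraries of t3. The share of higher calls was 22% at t4 and 18.0% at t6. It was 36.8% and 28.8% with median-ratio scaling, 43.1% and 44.2% after quantile normalization, and 51.8% and 46.1% with limma-voom. After quantile normalization it went from 87.4% to 71.3% at t3 and from 98.2% to 65.7% at t7. The median shift of all genes was −0.31 and −0.32 at these times. The IFN-gamma score was higher than in control at t2 (2.87 against 2.19, exact p = 0.00175), t4 (2.87 against 2.25, exact p = 0.00866; adjusted p = 0.0202) and t6 (2.48 against 2.05, exact p = 0.00216). At t1, t3, t5 and t7 exact p was 0.552, 0.242, 0.0758 and 0.0996.

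**Figure D3:**
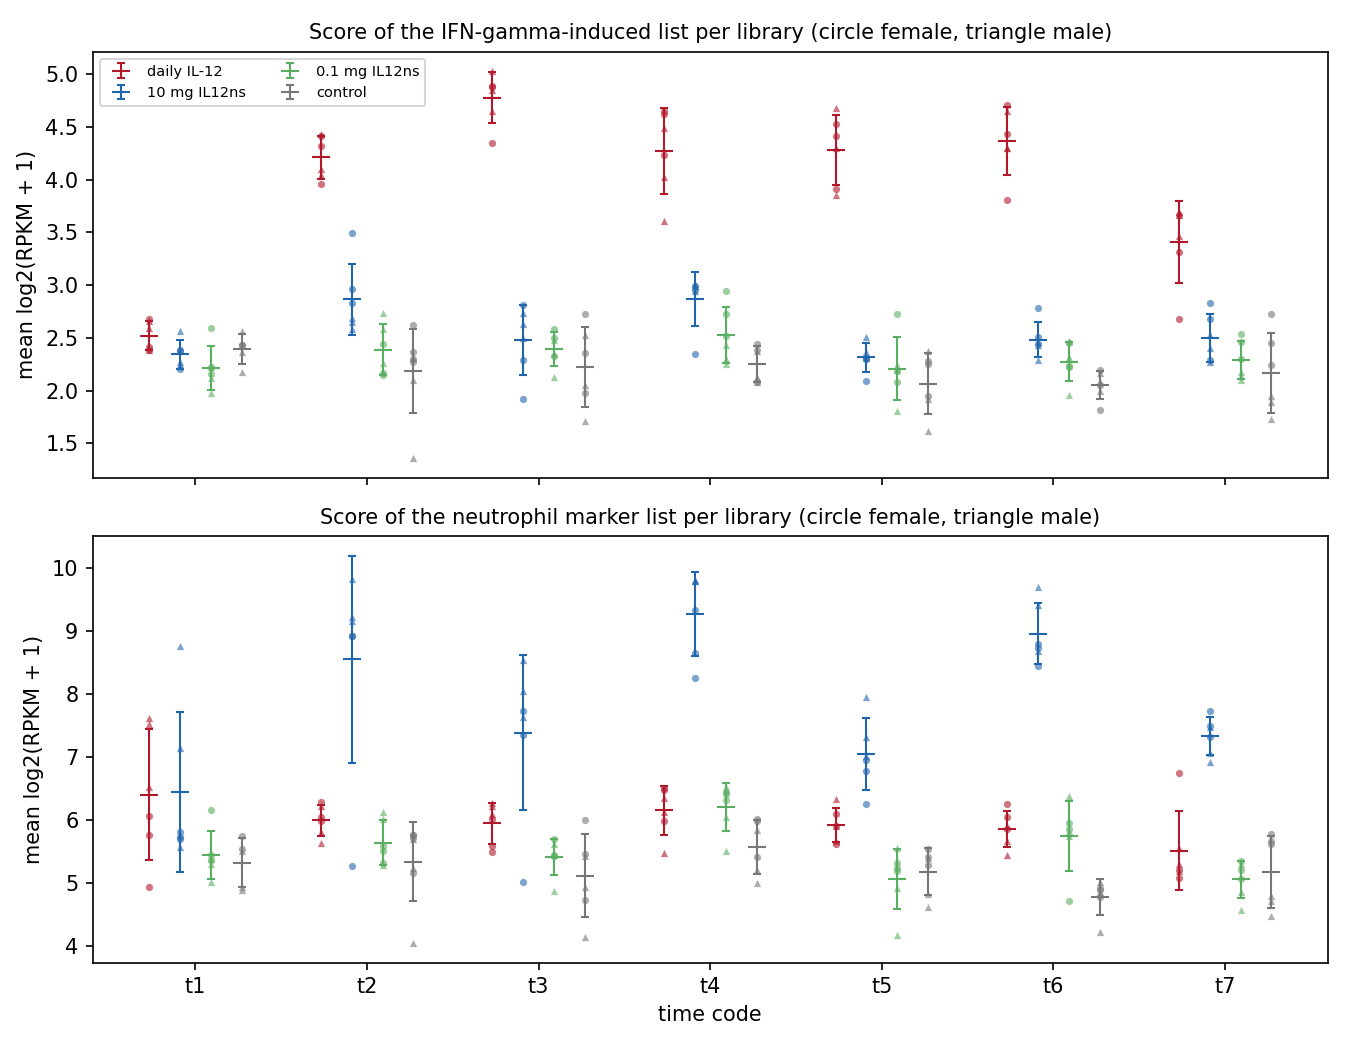
IFN-gamma and neutrophil scores of each library by arm and time, with mean and SD; at t6 the neutrophil score was 8.96 ± 0.48 at 10 mg, 5.75 ± 0.55 at 0.1 mg and 4.78 ± 0.29 in control.

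The 0.1 mg dose changed few genes in the fit of all libraries, and more at t6 in other fits. As the mean over times limma called 0 genes (3493 with an unadjusted p under 0.05, smallest adjusted p 0.0715), and limma-voom also called 0. At t6 11 genes rose and 0 fell (1071 with an unadjusted p under 0.05; 59 genes by limma-voom). Within the first run of library numbers, which holds all 12 libraries of t6 compared here, 147 rose and 0 fell. A fit of the compared arms only called 206 at t6 and 36 as the mean over times, and the fit without the 5 libraries least like their group called 128 at t6. Among them were Lrg1 (2.80 ± 0.57, adjusted p = 0.0108), a glycoprotein of neutrophils and the acute phase, and Lcn2 (2.19 ± 0.52, adjusted p = 0.0473). With them rose the metalloreductase gene Steap4 (2.0, adjusted p = 0.0257), Sema6b (1.88, adjusted p = 0.0128) and Socs3 (1.62), which curbs signals of IL-6 and G-CSF. The others were Soat2 (1.70, adjusted p = 0.00717), Entpd3 (1.64, adjusted p = 0.00716), the inhibitory receptor genes Lilr4b (1.61) and Lilrb4a (1.42), Kcnj2 (1.21) and Sycp2 (1.17). All 11 also passed at 10 mg at t6, where 5147 of 11734 genes passed, 929 of them higher. Both contrasts use the same control libraries, so this overlap is no separate support. Adjusted over the list alone 8 neutrophil markers were higher at t6 (1 over all genes, median 1.10). The neutrophil score was 5.75 ± 0.55 against 4.78 ± 0.29 in control (exact p = 0.013; adjusted p = 0.0273) and 6.21 against 5.58 at t4 (exact p = 0.0238; adjusted p = 0.0417). The IFN-gamma score did not pass at any time when all libraries of 2 groups were permuted (smallest exact p = 0.0455 at t6 and exact p = 0.0498 at t4, adjusted p = 0.095 for each). With permutation within sex it passed at t4 (adjusted exact p = 0.042).

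Lists at 0.1 mg, as the mean over times, held 0 genes past the threshold over all genes. Adjusted over the list alone the higher genes were 8 of 31 IFN-gamma-induced genes (median 0.15), 7 of 24 type I interferon-induced genes (0.15) and 6 of 14 of MHC class I processing (0.20, camera adjusted p = 0.0374, adjusted p = 0.801 with an estimated correlation). For neutrophil markers they were 9 of 13 (0.38, camera adjusted p = 0.112). With quantile normalization, median-ratio scaling and limma-voom the IFN-gamma median was 0.04, 0.06 and 0.07 and the type I interferon median 0.01, 0.02 and 0.03. The MHC class I median was then 0.10, 0.04 and 0.03 and the neutrophil median 0.28, 0.22 and 0.21. Relative to all genes, which shifted by 0.13, erythroid markers lay lower (median −0.14, camera adjusted p = 5.18e-15, and adjusted p = 0.014 with an estimated correlation), as did proliferation (−0.01, camera adjusted p = 3.27e-06, and adjusted p = 0.0234 with an estimated correlation). At t1, t2, t3, t4, t5 and t7 limma called 0 genes, with 516, 1439, 705, 821, 145 and 960 genes at an unadjusted p under 0.05. Limma-voom called 1 at t1 and 0 at the other 5 times. The effect differed between times for 0 genes (555 with an unadjusted p under 0.05, 0 by limma-voom). The smallest adjusted p values were those of Soat2 (0.135), Entpd3 (0.167) and Socs3 (0.336). Over t3, t4 and t6 within the first run of library numbers 180 genes passed, and within the second run 0.

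The doses of IL12ns were set against each other directly. Neutrophil markers were higher at 10 mg than at 0.1 mg in 13 of 13 cases (median 2.55, camera adjusted p = 6.37e-30, and adjusted p = 0.00183 with an estimated correlation). Over all genes the largest increases were Ngp (3.74), Stfa2 (3.61), Prok2 (3.58), Stfa3 (3.45) and Wfdc17 (3.42). B cell markers were lower in 14 of 14 cases (−1.26, camera adjusted p = 5.33e-08, adjusted p = 0.44 with an estimated correlation). Over all genes the largest decreases were Fcer2a (−1.56), Ptgs2 (−1.42), Fcmr (−1.37), Cd79b (−1.35) and Fcrla (−1.35). MHC class II presentation was lower in 11 of 12 cases (median −1.10, camera adjusted p = 2.61e-05, adjusted p = 0.598 with an estimated correlation). T cell markers were lower in 12 of 14 (−0.92, camera adjusted p = 0.0194, adjusted p = 0.71 with an estimated correlation). IFN-gamma-induced genes were higher in 13 and lower in 5 of 31 cases (median 0.15, camera adjusted p = 1.44e-07, adjusted p = 0.44 with an estimated correlation). In all 7832 genes passed, 1438 higher and 6394 lower at 10 mg. The share of higher calls was 18.4% as deposited, 33.4% with median-ratio scaling, 43.2% after quantile normalization and 45.6% with limma-voom, around a median shift of all genes of −0.20.

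Daily IL-12 and 10 mg IL12ns parted most in interferon-induced and neutrophil genes. IFN-gamma-induced genes were higher with daily IL-12 in 30 of 31 cases and lower in 1 (median 1.64, camera adjusted p = 1.88e-49, and adjusted p = 2.90e-04 with an estimated correlation). Over all genes the largest increases were Iigp1 (3.07), Ly6a (2.96), Serpina3g (2.47), Gbp5 (2.35) and Oasl2 (2.33). MHC class I processing was higher in 14 of 14 cases (median 1.11, and adjusted p = 0.0414 with an estimated correlation) and type I interferon-induced genes in 23 of 24 (1.0, and adjusted p = 0.00322 with an estimated correlation). Neutrophil markers were lower in 12 of 13 cases (−1.91, camera adjusted p = 1.48e-31, and adjusted p = 6.44e-04 with an estimated correlation). Over all genes the largest decreases were Prok2 (−3.58), Lcn2 (−3.28), Wfdc21 (−3.28), Stfa3 (−3.07) and Lrg1 (−3.04). MHC class II presentation was higher with daily IL-12 in 12 of 12 cases (median 1.0, camera adjusted p = 6.32e-06, adjusted p = 0.54 with an estimated correlation). So were cytotoxic effector genes (10 of 11, 0.59, camera adjusted p = 0.00252, adjusted p = 0.54 with an estimated correlation) and NK cell markers (13 of 15, 0.44, camera adjusted p = 0.0309, adjusted p = 0.567 with an estimated correlation). After quantile normalization the medians of cytotoxic genes and NK cell markers were 0.37 and 0.18. Nos2 (0.02, adjusted p = 0.874) and Lipg (0.06, adjusted p = 0.721) did not pass in the daily arm against control. In all 7723 genes passed, 6770 higher and 953 lower with daily IL-12. The share of higher calls was 87.7% as deposited, 67.7% with median-ratio scaling, 53.6% after quantile normalization and 55.9% with limma-voom, around a median shift of 0.22.

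The effect of 10 mg IL12ns differed between the sexes for 2943 genes, with the log2 fold change higher in males for 2744 and lower for 199. For genes that fell, a higher value in males is a weaker response. The smallest p value of this difference was that of Il13ra1, a receptor chain for IL-4 and IL-13 (2.47 in males, 0.87 in females, difference 1.60 ± 0.21, adjusted p = 4.06e-08). Next were Steap4 (3.45 and 1.5, difference 1.95 ± 0.26, adjusted p = 5.10e-08) and Sycp2 (1.49 and 0.26, difference 1.24 ± 0.17). Neutrophil markers had a median of 3.43 in males and 1.96 in females. The difference passed for 13 of 13 (median 1.36, camera adjusted p = 3.07e-09, adjusted p = 0.182 with an estimated correlation). Classical monocyte markers differed in 8 of 10 cases (0.94 in males and 0.25 in females, camera adjusted p = 0.00161, adjusted p = 0.577 with an estimated correlation). Type I interferon-induced genes were higher in males in 14 of 24 (0.52 and 0.11, camera adjusted p = 2.49e-04, adjusted p = 0.577 with an estimated correlation). Erythroid markers went the other way and were lower in males in 5 of 10 (−0.58 and −0.03, camera adjusted p = 1.67e-07, adjusted p = 0.18 with an estimated correlation). Limma-voom called 2712 genes for this difference, and fewer genes passed by limma without the 5 libraries least like their group. For daily IL-12 the difference passed for 3 genes, Adamts14 (0.83 ± 0.17), Samd3 (0.66 ± 0.14) and Klrg1 (0.90 ± 0.20; 1.28 in males, 0.38 in females), each with adjusted p = 0.0416. Limma-voom called 0 (2709 with an unadjusted p under 0.05 by limma). At 0.1 mg it passed for 0 genes (470 with an unadjusted p under 0.05, 0 by limma-voom), with the smallest adjusted p at 0.191 for Matn4. Tested in each sex alone, 4818 genes passed in males and 1755 in females for daily IL-12, 5748 and 5087 for 10 mg, and 24 and 2 for 0.1 mg. At 10 mg 2885 were higher and 2863 lower in males, and 720 higher and 4367 lower in females.

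**Figure D4:**
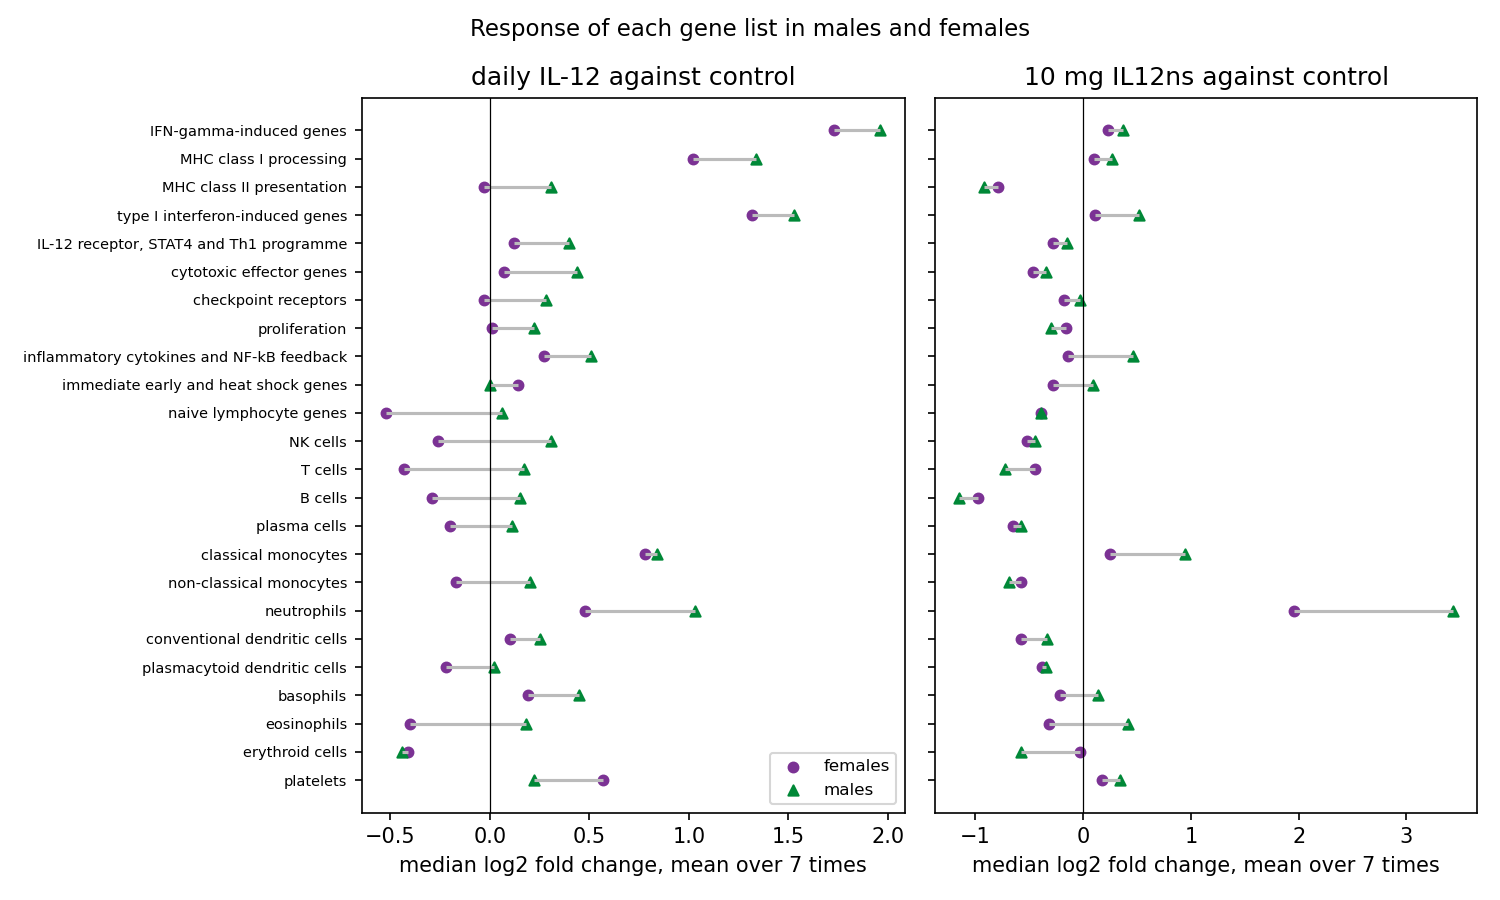
Median log2 fold change of each fixed list in males and in females, mean over the 7 times, for daily IL-12 and 10 mg IL12ns against control. Neutrophil markers at 10 mg lie at 3.43 in males and 1.96 in females.

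Within control 9 genes changed with time (722 with an unadjusted p under 0.05; 232 genes by limma-voom, 0 in a fit of the control arm alone). The smallest p value was that of Irf7, a switch of interferon genes (7.78 ± 0.53, mean ± SD, at t1 and 6.50 ± 0.56 at t3, adjusted p = 0.0065). Next were the collagen gene Col11a2 (2.47 ± 0.21 at t1 and 0.95 ± 0.28 at t5, adjusted p = 0.0067) and the lipoprotein lipase gene Lpl (0.31 ± 0.16 at t1 and 1.41 ± 0.49 at t7, adjusted p = 0.00832). These means are not corrected for the run of library numbers: all 5 control libraries of t1 come from the second run, all 6 of t3 and 5 of 6 of t5 from the first, and 5 of 6 of t7 from the second. Sex separated 2495 genes over all arms, 1243 higher and 1252 lower in males, and the run of library numbers 822 genes.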

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

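The tests of other splits of the libraries, of the 3 libraries with unlike Lipg levels and of the male library of t1 were chosen after the results were seen.

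A Dixon test of 56 group scores picked out 8 scores, from 7 libraries, far from the rest of their group, where about 1 in 20 groups would show one by chance. For the IFN-gamma score these were replicate 6 of 10 mg at t4 (2.35, others 2.94 to 3.01) and replicate 6 of control at t2 (1.36, others 2.10 to 2.62). For the neutrophil score they were replicate 1 of 10 mg at t3 (5.01, others 7.35 to 8.54), replicate 2 of 10 mg at t2 (5.26, others 8.92 to 9.83), replicate 3 of 0.1 mg at t3 (4.87, others 5.42 to 5.69), replicate 3 of control at t6 (4.22, others 4.78 to 5.02), replicate 4 of daily IL-12 at t7 (6.75, others 5.07 to 5.56) and replicate 6 of control at t2 (4.04, others 5.16 to 5.76). Some of these libraries were low over all tested genes, so part of their low score may not be particular to the list. The median log2 level was 1.67 in replicate 6 of 10 mg at t4 (others 2.02 to 2.42). It was 1.44 in replicate 6 of control at t2 (others 2.39 to 3.18) and 1.78 in replicate 1 of 10 mg at t3 (others 2.56 to 3.12). Their 20 highest genes held 45.5%, 54.4% and 53.5% of the summed RPKM.

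Of these libraries, 2 of the 10 mg arm lack the neutrophil response of their group, and that of t2 also its Lipg response. Lipg, at most 0.62 in any library of the other arms, was 0.06 in replicate 2 at t2 (5.87 to 6.58 in the other 5) and 0.00 in replicate 1 at t3 (only 0.20 to 0.61 in the other 5), and both libraries correlated best with a group of the 0.1 mg arm (0.974 and 0.926, against 0.898 and 0.881 with their own group). In the other direction, replicate 2 of 10 mg at t1, a male, had Lipg at 3.35 where the other 5 of its group had 0.00; Prok2 was also raised, and the library had its best correlation with 10 mg at t4 (0.967, against 0.927 with its own group). Its Lipg lies below the lowest library of t4 and t6 (4.96), and its sex and that of replicate 2 at t2 differ, so these libraries are not a simple exchange of labels with each other. Replicate 2 at t2 still had an IFN-gamma score of 3.49, the highest of the 10 mg arm and above every library of control (at most 2.73) and 0.1 mg (at most 2.94), which argues against a missed dose and against a control or 0.1 mg label. A daily IL-12 label stays open, since its scores lie within those of daily IL-12 at t7 (2.68 to 3.69, neutrophils 5.07 to 6.75), though its IFN-gamma score is below those at t2 (3.96 to 4.43). Replicate 1 at t3 had 1.92, so for it a missed dose or a label stays open. The make-up of that library was also unlike its group, with 53.5% of summed RPKM in 20 genes against 19.4 to 34.4% in the others. A label or carried-over material stays open for replicate 2 at t1. None of these was tested. Without the 5 libraries least like their group, which include both of the low ones, the 10 mg arm had 5348 genes at t2 and 2838 at t3.

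The effect of daily IL-12 differed between times for 344 genes. The splits exchange arm labels, which removes the arm effect itself. They therefore cannot exclude chance for a difference of that effect between times (5 of 100 gave as many, highest other 4571). Single genes passed the F test by a wide margin (Il10, adjusted p = 2.30e-28). The effect of 10 mg differed between times for 2088 genes, and for the same reason the splits (3 of 100, highest other 3947) do not decide on this count. Between sexes the effect of daily IL-12 differed for 3 genes (3 of 100 splits, highest other 2878), but the count fell to 0 with no filter, with a mean RPKM of at least 5, with a fit of the compared arms and with limma-voom, so it carries little weight. For 10 mg it differed for 2943 genes (2 of 100 splits, highest other 4952), and for fewer without the 5 libraries least like their group. Splits that call several times the real count, as for daily IL-12 here, point to a structure of the samples.

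The difference between 10 mg and control was larger in males than in females in all 13 neutrophil markers, by a median of 1.36 (camera adjusted p = 0.182 with an estimated correlation). The tables argue against a few odd libraries as the whole cause: the difference was 1.07 without the 5 libraries least like their group and 1.04 without the 3 with unlike Lipg levels. The same list difference was 0.56 for daily IL-12 and 0.44 for 0.1 mg, and the mean neutrophil score of control was lower in males than in females at each time. At t7 the 10 mg males (6.92 to 7.47) did not lie above the 10 mg females (7.32 to 7.73). Control males had 4.48 to 4.79 there and control females 5.62 to 5.78. The 10 mg difference was above 0 at 7 of 7 times, which argues against 1 or 2 times as the source, but at t7 it came from control. The 7 times may share animals and are not separate evidence of a sex difference. A difference between the sexes that was already present at t1 may be part or the whole of it, since the median at t1 was 2.01, and 1.51 without the male library with high Lipg, against a mean of 1.27 over t2 to t7; 0 genes passed at t1 and 859 had an unadjusted p under 0.05, with 2 to 3 libraries per sex. Whether t1 precedes the first dose is not stated, so a sex difference in the response and one in the resting blood of these animals both stay open.

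At 0.1 mg, 11 genes rose at t6. The rise was spread over more than 1 or 2 libraries, since 10 of the 11 had at least 4 of 6 libraries above the highest control. The genes were picked for being higher in these same libraries, which favours such a count, so it is no separate support for the rise. A 10 mg library of t6 under a 0.1 mg label is unlikely, since 0 of the 6 libraries had a neutrophil score at or above the lowest 10 mg library of t6 (highest 6.38, against 8.44). The test does not cover 10 mg libraries of other times, some of which score as low, such as replicate 5 at t5 (6.25). Few splits gave as many genes (3 of 100, real 11, highest other 4516). This share is not adjusted over the comparisons, so chance is unlikely but not excluded. The highest count points to a structure of the samples. Control had its lowest mean neutrophil score at t6 (4.78, against 5.11 to 5.58 at the other times). The 0.1 mg score at t6 (5.75) lay below that at t4 (6.21), so part of the difference at t6 may lie in control. A weak neutrophil response to the low dose stays open as a hypothesis, as does a varying carry-over of neutrophils into the mononuclear preparation, which was not tested.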

How the results depend on the processing

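The alternatives moved many counts, and changed most of the list calls, the share of higher genes and the sign of a few named genes. The number of 10 mg genes at t3 ranged widely, and the scaling between libraries moved the balance of higher and lower genes. Median-ratio scaling, limma-voom and leaving out 5 libraries were added after the data were seen. The cause of each move was not tested, except that fewer genes can pass where fewer are tested. Counts below are of genes past an adjusted p of 0.05, against control unless said, under each setting instead of the reported ones.

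With a correlation estimated from the data, camera called fewer lists: 3 instead of 10 for daily IL-12 as the mean over times, and at t1 to t7 0, 5, 5, 3, 3, 3 and 3 instead of 5, 8, 12, 8, 6, 11 and 8. For 10 mg these were 1 instead of 12, and 0, 1, 0, 1, 2, 1 and 1 instead of 11, 6, 12, 7, 13, 7 and 9. For 0.1 mg they were 2 instead of 7, and 0, 0, 1, 1, 1, 0 and 0 instead of 5, 10, 4, 10, 10, 9 and 6. Between doses 1 list was left of 7, and between daily IL-12 and 10 mg 4 of 9.

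With a fit of the compared arms only, 0.1 mg had 36 genes as the mean over times, 206 at t6 and 23 differing between times; 10 mg had 35 at t3, 10 at t5 and 1215 differing between times; daily IL-12 had 1 at t1 and 0 differing between sexes, and control had 0 changing with time.

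With limma-voom, 0.1 mg had 1 at t1 and 59 at t6; 10 mg had 628 at t1, 5036 at t2, 1421 at t3, 1.1e+03 at t7 and 4298 differing between times. Daily IL-12 had 1546 at t4 and 0 differing between sexes, and control 232.

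With genes of a mean RPKM of at least 5, daily IL-12 had 187, 332, 320 and 78 at t4 to t7, 150 differing between times and 0 between sexes. The 10 mg arm had 3377 as the mean over times, 0 at t1, 1596 at t2, 2576 at t4, 8 at t5, 2526 at t6 and 1292 differing between times. The 0.1 mg arm had 1 as the mean over times and 70 at t6. Between doses 3660 passed, between daily IL-12 and 10 mg 3745, and in control 3.

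With median-ratio scaling, daily IL-12 had 1750 at t4, 217 at t7 and 21 differing between sexes. The 10 mg arm had 595, 4744 and 1631 at t1 to t3, 50 at t5, 1493 at t7 and 4559 differing between times. The 0.1 mg arm had 26 at t6, and control 270.

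With quantile normalization, daily IL-12 had 1478 at t4, 739 at t6, 213 at t7 and 13 differing between sexes. The 10 mg arm had 625, 3879 and 1575 at t1 to t3, 48 at t5, 1490 at t7 and 3327 differing between times. The 0.1 mg arm had 27 at t6 and 2 at t7, and control 350.

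With no filter on low values, 0.1 mg had 55, 3, 35, 8 and 5 at t1 to t5 and 17 at t7; 10 mg had 69 at t1. Daily IL-12 had 56 at t1, 196 at t7 and 0 differing between sexes, and control 116.

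With no term for the run of library numbers, 10 mg had 2214 at t3, 152 at t5, 224 at t7 and 4432 differing between times. Daily IL-12 had 929 at t6 and 71 differing between sexes, 0.1 mg had 1 at t5, and control 774.

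With a pseudocount of 0.1, 0.1 mg had 1 as the mean over times, 52 at t6 and 1 differing between times; 10 mg had 0 at t1 and 16 at t5, and daily IL-12 had 7 differing between sexes.

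Without the 5 libraries least like their group, 10 mg had 43, 5348 and 2838 at t1 to t3, 56 at t5, 4642 differing between times and 1.9e+03 between sexes. Daily IL-12 had 412 at t2, 844 at t4 and 769 at t6. The 0.1 mg arm had 128 at t6 and 1 differing between sexes, and control 50. Leaving out 1 library of t1 at a time gave 0 to 73 genes for 10 mg and 0 to 1 for daily IL-12. No gene was left at 10 mg at t1 without replicate 1, 2, 3 or 5 of control or replicate 1 or 2 of 10 mg; the highest count came without replicate 6 of 10 mg, and for daily IL-12 without its replicate 3.

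With permutation within sex, the IFN-gamma score at 0.1 mg at t4, 0.28 above control, passed with an adjusted exact p of 0.042. Of the named genes, Psmb10 (0.02) and Hbb-bs (0.01) between doses with limma-voom changed sign, as did Cd244a (−0.00 with quantile normalization, −0.03 with limma-voom) and Pacsin1 (−0.01 with quantile normalization) between daily IL-12 and 10 mg.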

Other observations

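The tests of t6 against t7, of other cell types at t4, of daily IL-12 at t7 and of other splits of the libraries were chosen after the results were seen.

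The neutrophil genes of the 10 mg arm were higher at t2, t4 and t6 than at t3, t5 and t7. The 2 runs of library numbers do not produce this, since t6 lay above t7 within 1 run (8.96 ± 0.48 against 7.33 ± 0.30, exact p = 0.00216). A lower share of lymphocytes would raise the markers of all other cells about alike, but the highest median among 8 other cell type lists at t4 was 0.96, for platelets, against a lower quartile of 3.48 for neutrophils. The rise and fall may follow the schedule of dosing and bleeding, which the files do not give, and this stays a hypothesis from the same data. A mononuclear preparation normally removes most neutrophils, so low-density neutrophils or a varying carry-over in the preparation also stay open, and neither was tested.

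Genes of primary granules, made by early precursors in the marrow, had a median log2 fold change of 0.45 at 10 mg over 4 genes (Ctsg 0.25, Elane 0.41, Mpo 0.48 and Prtn3 1.51, all past the threshold). The value lies under the bound of 0.5 set beforehand for no entry of precursors, but that bound does not suit genes so low: mean RPKM was 0.436 against 0.0213 in control for Elane, 0.692 against 0.126 for Mpo and 3.22 against 0.365 for Prtn3, and log2(RPKM + 1) understates such changes. An entry of precursors therefore stays open. The wording of that bound was changed for a short time after the value was seen and then put back.

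The IFN-gamma score with daily IL-12 was lower at t7 than at t6 by 0.96 (exact p = 0.00216), so the response may wane, or the last bleed may come longer after a dose. In the 10 mg arm 32 of 36 libraries from t2 to t7 lay above the median of the 0.1 mg libraries of their time. The permutation p was 5.00e-05 from 100000 resamples, so the score was mostly higher at the high dose. Its members differed: between doses Gbp2b (1.41), Nos2 (1.28) and Gbp2 (1.27) were higher at 10 mg. The mean log2 level of Iigp1 was 0.64 at 10 mg and 0.72 at 0.1 mg, and that of Cxcl9 0.07 and 0.04. The score passed against control only at t2, t4 and t6, where neutrophil scores were also highest. Whether it followed neutrophil content rather than IFN-gamma was not tested. Against control the score of the 10 mg arm did not pass at t3, t5 and t7 (exact p = 0.242, 0.0758 and 0.0996), the list lost its call with an estimated correlation (adjusted p = 0.396), and animals cannot be counted without their names.

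For each count of genes, 100 splits of the same libraries into groups of the same sizes, the real one included, were compared with the real split. Chance is called unlikely where fewer than 5 of the 100 gave as many genes. This bound is not adjusted over the comparisons, so it does not exclude chance. Splits between arms exchange labels at all times at once in the fit of all libraries. A strong arm effect at other times then widens the spread of a split and can lower its count at a given time. No split keeps the libraries of 1 animal together, although libraries of different times may share an animal. For daily IL-12 as the mean over times chance is unlikely (2 splits as large, real 4217, highest other 6365). The same holds at t2 (2, 766, 6647), t3 (4, 1687, 7778), t4 (1, 331, 44), t5 (2, 516, 2523), t6 (1, 486, 349) and t7 (4, 124, 4995). At t1 the real count is 0, which every split reaches, so the 100 of 100 decides nothing (highest other 342). For the count of genes whose daily IL-12 effect differs between times chance cannot be excluded (5, 344, 4571). Exchanging arm labels removes the arm effect itself, so these splits do not test its difference between times. The 3 genes that differ between sexes (3, 3, 2878) were 0 under 4 other settings, so that test carries little weight.

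For 10 mg chance is unlikely as the mean over times (1, 6789, 4306) and at t2 (2, 2532, 3253), t4 (1, 5188, 4943) and t6 (1, 5147, 3419). At t5 (1, 31, 18) and t7 (1, 504, 1) no other split gave as many genes. The large effects of t2, t4 and t6 enter the spread of these splits, so they do not decide on t5 and t7. Chance cannot be excluded at t3 (15, 744, 6692), where replicate 1 is unlike its group. At t1 the split test (1; 1, 0) rests on 1 gene, which is lost without any of 6 single libraries and with a pseudocount of 0.1, so it carries little weight. For effects that differ between times (3, 2088, 3947) the splits do not decide, for the reason given for daily IL-12. For effects that differ between sexes few splits gave as many genes (2, 2943, 4952), though exchanging sex labels also removes sex differences shared by both arms. Sex labels were exchanged within each arm and time, which parts libraries that may come from 1 animal. These splits therefore cannot tell a sex effect from lasting differences between a few animals.

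For 0.1 mg chance is unlikely at t6 (3, 11, 4516). In its other comparisons the real count is 0, which all 100 splits reach, so they decide nothing. Their highest counts were 6009 as the mean over times, 1, 6182, 5015, 67, 2765 and 1417 at t1 to t5 and t7, 6520 between times and 6316 between sexes. Between doses (1, 7832, 4361) and between daily IL-12 and 10 mg (1, 7723, 2187) chance is unlikely. For change with time in control it cannot be excluded (15, 9, 6965). The splits that call several times the real count point to a structure of the samples, whose source was not tested.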
